A study of Sus scrofa with 4 samples.

How the data were processed

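Histone H4 lysine 12 lactylation (H4K12la), an acyl mark that cells derive from lactate, was profiled by chromatin immunoprecipitation and sequencing in the livers of sows in late gestation. The labels give a low (normal) and a high bile acid group, with 1 immunoprecipitated library and 1 input library in each, 4 samples in total. Group membership was taken from the sample titles, and replicate numbers were given in accession order. Per the labels' protocols, chromatin was crosslinked in formaldehyde (1%) and sheared by 8 min of sonication, 10 ng of DNA entered each library, amplification took 13 cycles, and fragments of 250 to 450 bp were selected. The antibody was directed against H4K12la. The cell type was labelled hepatocytes and the sex female.

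The deposited data analysed here were 2 lists of narrow peaks, 1 for each immunoprecipitated library; the input libraries entered only through the background of the peak caller. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0. The notes name both the human build hg38 and the pig build Sscrofa11.1. The peaks lay on chromosomes 1 to 18, X and Y, and their largest coordinates fell close to the last annotated gene of each Sscrofa11.1 chromosome, so pig coordinates were used throughout. In the deposited lists the fold enrichment at the summit, a ratio over the local background, and the −log10 p-value and −log10 q-value of each peak are the authors' own values. The deposited score of each peak is a display value derived from its p-value and was not used. The caller's cutoff is not given in the sources used here, but the largest p-value was 0.00989 in both lists. Peaks were called for each library on its own, with no pooling.

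Gene names and positions came from the RefSeq table of Sscrofa11.1, which holds 28210 annotated genes on these chromosomes, 16303 of them protein-coding with a symbol. A further 3230 coding genes with a provisional LOC name were left out. The table gives the start and end of each gene but no strand and no exons. Promoters could therefore not be set apart from transcript ends, and the planned promoter window was replaced by a gene-end window of 1 kb on either side of either gene end. One of these ends holds the start site. Exons, introns and untranslated regions were not told apart. No genome sequence was used here, so the planned motif and repeat shares, the shuffling outside assembly gaps and the matching of random gene lists on GC content were not run; random lists were matched on 10 classes of gene length in place of GC content.

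Peaks of the lists were called shared with an overlap of at least 1 bp. Overlap was compared with 1000 random placements of the low list on the same chromosomes, and, as a choice made after the data were seen, with 1000 placements that moved each peak by 50 to 500 kb. Shares carry exact Clopper-Pearson 95% intervals, and fragment counts carry exact Poisson 95% intervals. All intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules. With 1 library per group, no p-value between groups was computed, and no difference between the groups has a replicate check. The p-values and q-values printed for peaks are those of the authors' caller. They compare a library with its own input.

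Each of 29 gene lists fixed before the data were examined was described by its number of members with a gene-end peak and by the percentile of that number among 10000 random lists of the same size. These lists were the AP-1 family, the JNK and MAPK pathway, bile acid synthesis, transport, signalling and detoxification, glycolysis and lactate, lactylation writers and erasers, gluconeogenesis and urea cycle, lipid and cholesterol, oxidative stress, apoptosis and ER stress, inflammation, fibrosis, cell cycle, markers of 7 liver or blood cell types, and 7 gene families defined by symbol. A further family, olfactory receptors, had no measured member. Of 696 listed symbols, 680 were found in the annotation. For percentiles, random lists tied with the observed count were split evenly above and below it. The genes named in the text follow a rule set at the same time. It took 11 genes whatever their values (JUN, FOS, CYP7A1, CYP8B1, NR1H4, NR0B2, ABCB11, SLC10A1, LDHA, EP300 and ALB), the 8 genes with the highest fold at a gene end in each of the classes high only, low only and both, and up to 3 members of each list by fold, high only first. This gave 100 genes, of which a few are not reported here. Members named in addition, to complete counts of 5 or fewer or to list bile acid genes, were chosen after their values were seen.

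Library depth is not in the labels. It was recovered from the lists, because MACS2 computes the fold and the p-value from the number of fragments at the summit and the expected number. Solving both for each peak gave whole fragment numbers for 100% of peaks in either list, within a tolerance of 0.002 in −log10 p. In the low list this held only with the immunoprecipitated pileup multiplied by 0.881; without that factor 0.907% of peaks were solved. The high list needed no such factor, and its input was multiplied by 0.950. The immunoprecipitated libraries came out at 7.37 (low) and 6.71 (high) fragments per kb, and the inputs at 6.49 and 7.07 fragments per kb. These are per kb of the genome size set in the caller, which was not recovered here. Ratios between the libraries take that setting to be the same for both lists. The median summit held 10 fragments in the low list and 9 in the high list, so most single peaks rest on few fragments.

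Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap code was tested on simulated intervals, where 0 of 4000 calls differed from an exhaustive search. The recovery of fragment numbers was tested on simulated peaks and returned the exact number for 100% of 1994 peaks with low-list settings and for 100% of 1999 with high-list settings. For the high list, with its 16303 genes, gene lists of 20 members were simulated. They reached percentile 95 in 4.8% of cases at the background rate. At 2 and 3 times that rate they did so in 65.2% and 97.8% of cases. The random lists of this test were not matched on gene length, unlike those behind the reported percentiles. Alternatives covered the q and fold thresholds, the definition of overlap, the length of the high list, the window at gene ends, the choice of random lists and the JUN window.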

Results

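H4K12la was mapped in the liver of late-gestation sows of a low (normal) and a high bile acid group, with 1 immunoprecipitated library and 1 input library per group and no replicates. The series asks which genes carry the mark when bile acids are high, and its title names c-JUN signalling and intrahepatic cholestasis of pregnancy, a disorder of bile flow in late gestation. All coordinates are Sscrofa11.1, folds are the authors' enrichment at the summit over the local background, and q is the authors' value for each peak. The sequencing depth recovered from the lists was 7.37 immunoprecipitated fragments per kb in the low library and 6.71 in the high library. Here a kb is counted by the genome size set in the caller, which was not recovered.

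The first comparison asked how much of the genome was called in each group and where. Summits were placed against all 28210 annotated genes of any type. Called peaks gathered at gene ends in both lists. Moved peaks were not matched on GC content, so this gathering was not separated from other properties of gene ends. In the high list, 11.4% of the summits (3234 of 28283; 95% interval 11.07 to 11.81%) lay within 1 kb of a gene end, against 5.73% when peaks were moved by 50 to 500 kb. In the low list, 10.4% did so (597 of 5735; 9.63 to 11.2%), against 5.42% after moving. Gene interiors held 56.5% of the high and 57.0% of the low summits, close to the 57.7% and 58.6% of moved peaks. Intergenic sequence held 32.1% and 32.6%, against 36.6% and 36.0%. Among the 608 high-list peaks with q under 0.05, the share at gene ends was 20.1% (17.0 to 23.5%), and among as many low-list peaks of smallest p it was 13.3% (81 peaks; 10.7 to 16.3%). The low list had 13 peaks with q under 0.05, none of them at a gene end. A set of 608 peaks is a larger part of the shorter low list, and the share at gene ends rises with rank by p in both lists. The 20.1% and 13.3% are therefore not at like stringency.

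The high list was 4.93 times as long as the low list, with 28283 against 5735 peaks, and covered 11.09 Mb against 2.12 Mb. Peaks were of like width, with medians of 355 and 338 bp, and of like fold, with medians of 2.90 and 2.98. At q under 0.05, 2.15% of the high list (1.98 to 2.33%) and 0.227% of the low list (0.121 to 0.387%) remained, and 97.4% of the low list had a q of 1. As recovered from the lists, the caller had multiplied the low library's pileup by 0.881 before testing and had left that of the high library as it was.

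**Figure D1:**
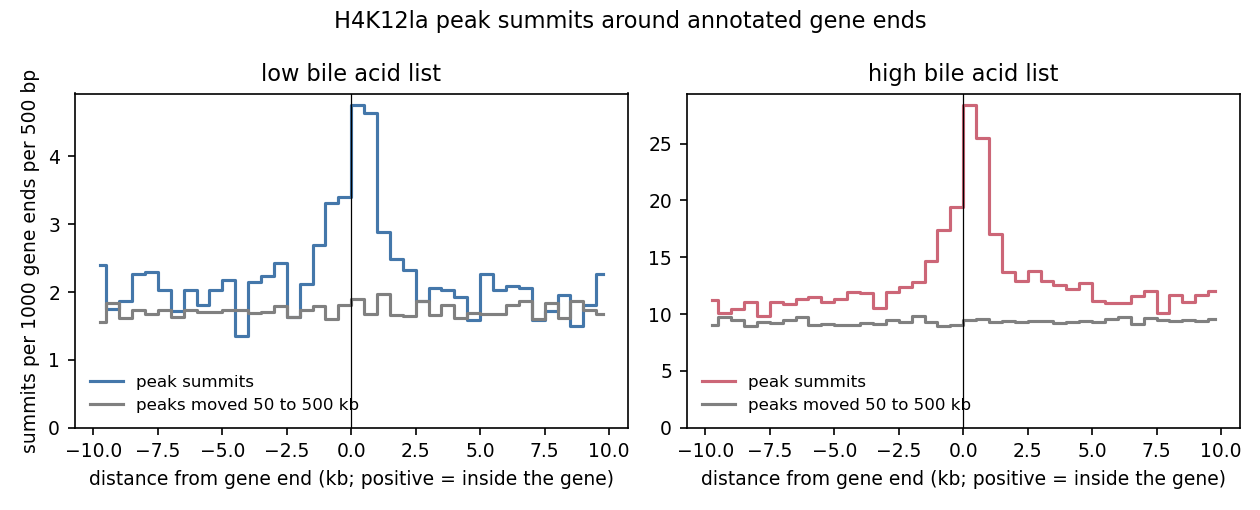
Peak summits per 1000 ends of the 16303 named coding genes in bins of 500 bp (y axis, a separate scale for each list). The x axis gives the distance from the gene end in kb, with positive distances inside the gene. Coloured lines are the observed summits of the low (left) and high (right) bile acid lists. Grey lines are the same peaks moved by 50 to 500 kb. Both lists rise above the grey line around the gene end, more on the side inside the gene.

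The next comparison asked which genes carried a gene-end peak in either liver. Of 16303 named coding genes, 3004 (18.4%) had one in the high list and 585 (3.59%) in the low list, each 2.20 times the number reached when the peaks were moved by 50 to 500 kb. Of these genes, 144 were in both lists, against 107.8 if the lists were independent, 2860 in the high list only and 441 in the low list only. The strongest genes of the high list only were CBR4, which encodes a carbonyl reductase, with a fold of 5.37 (q 0.000364) at chromosome 14, 20622643 to 20623081, and ID2, an inhibitor of basic helix-loop-helix transcription factors, with a fold of 5.03 (q 0.00241) at chromosome 3, 127499257 to 127499926. NEUROG2 followed at 4.84, LIMD1, PIGL and RGS3 at 4.79, MAPKAPK5, a kinase downstream of MAP kinases, at 4.72 and IRF2BPL at 4.71. These 8 genes each had 14 to 16 fragments at the summit. The strongest genes of the low list only were POLR1D, a subunit of RNA polymerases I and III, with a fold of 4.59 (q 0.0533) at chromosome 11, 5043786 to 5044191, and GSTO1, a glutathione transferase, at 4.53 (q 0.142). CFAP61 and CRNKL1, which share 1 peak, FBXW11, NACA, PIK3CB and SKIDA1 each had a fold of 4.23 (q 0.598). Genes with a gene-end peak in both lists, where the peaks need not overlap, were led by CDC42EP5 and LENG9, neighbours that share 1 high-list peak of fold 5.39 and 1 separate low-list peak of fold 2.67. The peaks overlapped at STAM, with folds of 4.88 (high) and 2.63 (low), and at PDLIM2, with 4.34 and 2.94. They did not overlap at CRLS1, the cardiolipin synthase gene (4.70 and 3.86), at C3H2orf91, where they lay at opposite gene ends (4.32 and 3.60), or at the neighbours C18H7orf49 and TMEM140 (4.16 and 2.94).

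At the level of positions, 208 low-list peaks (3.63%; 3.16 to 4.14%) overlapped 207 high-list peaks (0.732%; 0.636 to 0.838%). Random placement of the low list gave 56.2 ± 7.35 (SD of 1000 placements), so the overlap was 3.70 times that of chance. It was 2.88 times that of peaks moved by 50 to 500 kb. Shared peaks lay at gene ends in 31.4% of cases on the high side (65 of 207; 25.1 to 38.2%). A peak called in 1 list only is a difference of calls at the caller's cutoff, not a tested difference in occupancy. Of the 28076 high-list peaks without an overlap, 84 had a fragment count whose 95% interval lay at or above the fewest fragments that the caller would have accepted in the low library over the same expected pileup. By the limit of the high library, 376 of the 5527 low-list peaks without an overlap did so. Of 73 high-only genes taken by the naming rule, the 8 of highest fold met the low library's limit in this way and the rest did not. None of these counts was compared with what chance would give.

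Peak density was also compared between chromosomes. Autosomes carried 12.5 peaks per Mb in the high list and 2.53 in the low list, and chromosome 12 was the densest in both, at 23.1 and 3.67 per Mb. Chromosome X carried 0.421 and 0.0318 per Mb, and chromosome Y 0.185 and 0.0231 per Mb. The samples are labelled female.

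**Figure D2:**
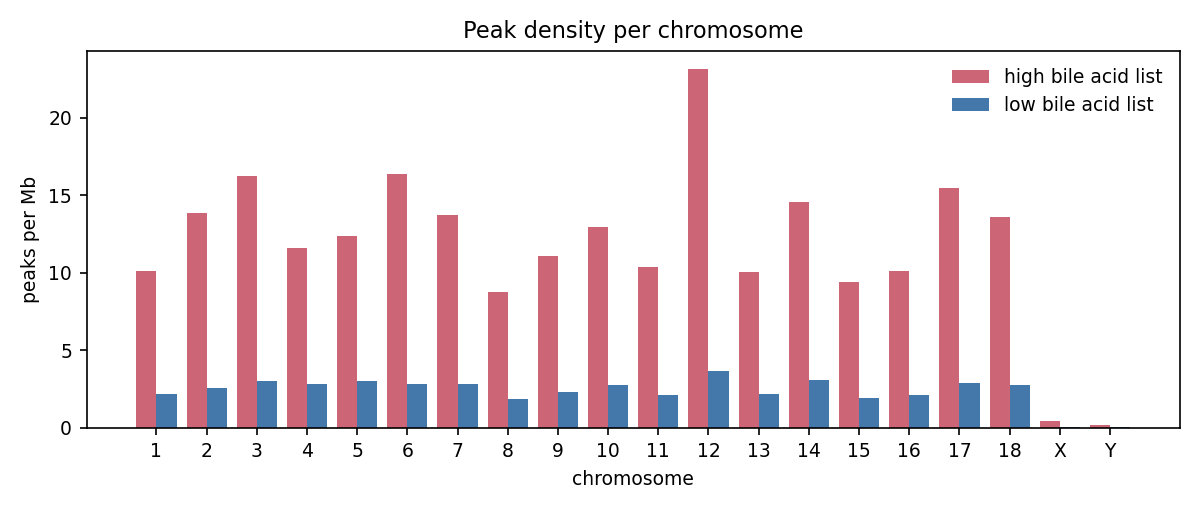
Peaks per Mb (y axis) on each chromosome of the pig genome (x axis) in the high (red bars) and low (blue bars) bile acid lists. Chromosome 12 is the densest, at 23.1 and 3.67 peaks per Mb, and X and Y hold few peaks in either list.

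The title of the series names c-JUN, so the JUN locus was described next. JUN, which encodes a subunit of the AP-1 transcription factor, lies at chromosome 6, 153686425 to 153687635, and carried 1 peak in the high list and none in the low list within 10 kb. That peak spans 153686914 to 153687402, inside the gene, with a fold of 3.19, p of 2.12e-05 and q of 0.157. It rested on 12 fragments at the summit (95% interval 6.20 to 21.0) over 3.08 expected. In the low library, at least 10 fragments over the same expected number would have been needed for a call, within that interval. The missing low-list call therefore does not show a difference at JUN, and the low library's count there is not in the lists. FOS, the usual partner of JUN, had no peak within 10 kb in either list. Of the 20 AP-1 family genes, 5 had a gene-end peak in the high list (percentile 75 among random lists) and none in the low list (percentile 25.1). Besides JUN, they included FOSL1 with a fold of 3.78 (q 0.0736), FOSL2 and MAFG. Of 31 genes of the JNK and MAPK pathway, 5 had a gene-end peak in the high list (percentile 41.8). None had one in the low list (percentile 15.9). Folds were 3.35 for MAP2K3, 3.12 for MAPK14, which encodes p38 alpha, and 2.78 for MAP2K1, and MAP3K1 and MAP3K5 were the others. MAPK8, MAPK9 and MAPK10, which encode the JNKs, had no gene-end peak in either list, nor had MAP2K4 and MAP2K7.

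**Figure D3:**
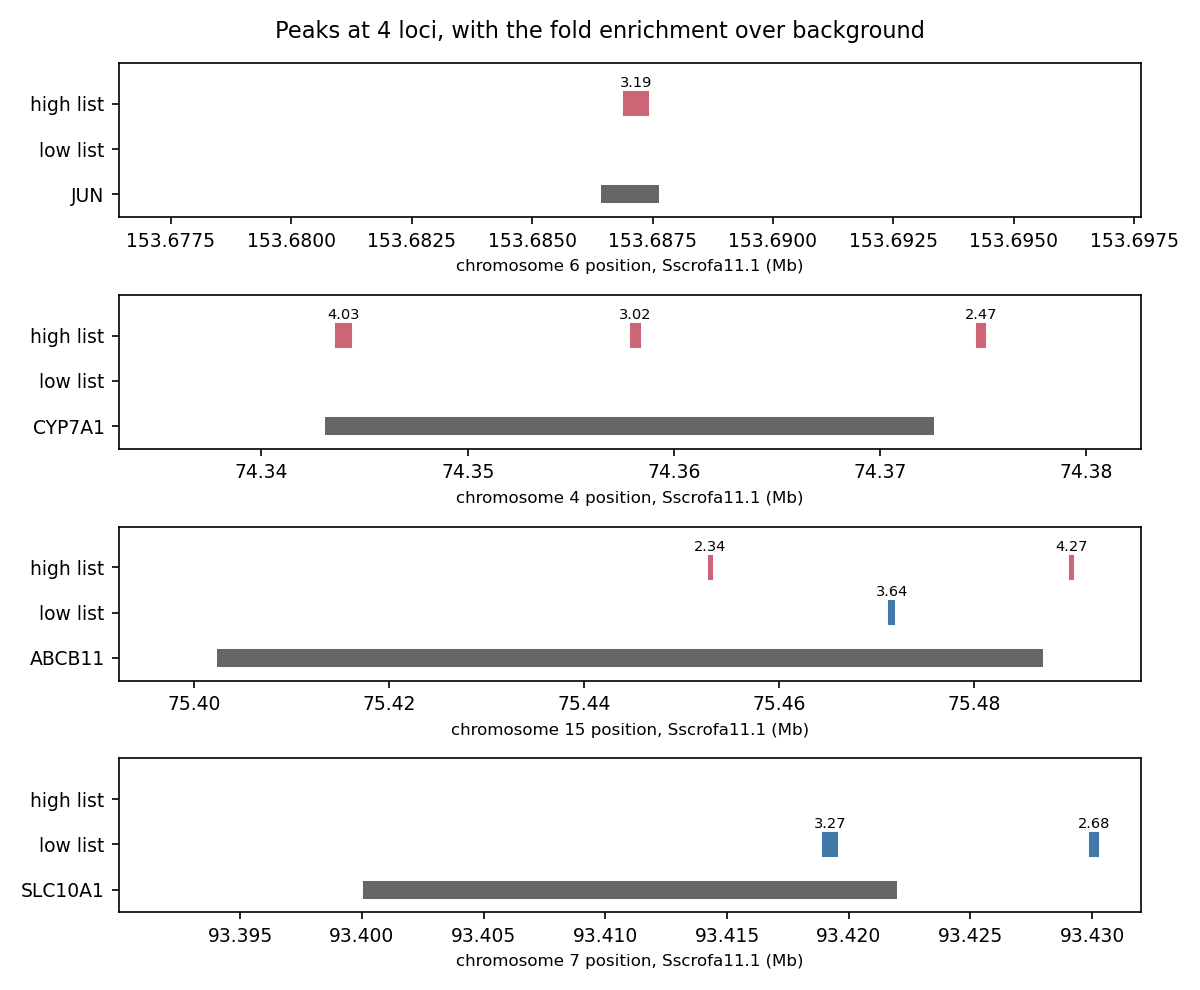
Peaks within 10 kb of JUN, CYP7A1, ABCB11 and SLC10A1 along chromosomes 6, 4, 15 and 7 (x axis, position in Mb); red bars are high-list peaks, blue bars low-list peaks and grey bars the annotated gene, and the number above each peak is its fold. JUN has 1 high-list peak, CYP7A1 has 3, ABCB11 has 2 high-list peaks and 1 low-list peak, and SLC10A1 has 2 low-list peaks.

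Genes of bile acid metabolism were compared because the groups differ in bile acids. Bile acid synthesis had the highest share of the lists in the high list, with 6 of 14 genes carrying a gene-end peak, against 2.63 on average in random lists (percentile 97.9). In the low list it was 0 of 14, where random lists gave 0.509 on average (percentile 29.9). The 6 genes of the high list were CYP7A1, the rate-limiting enzyme of the classic pathway, HSD17B4, AMACR and SCP2 of peroxisomal side-chain shortening, and SLC27A2 and SLC27A5, acyl-CoA synthetases. CYP7A1, at chromosome 4, 74343101 to 74372628, had 3 high-list peaks within 10 kb. The strongest spans 74343628 to 74344329, with a fold of 4.03 (q 0.0736) from 11 fragments (95% interval 5.49 to 19.7) over 1.98 expected. A call in the low library needed 7, within that interval, so the missing low-list call does not show a difference at CYP7A1. SLC27A2 had a fold of 3.39 (q 0.167) and HSD17B4 one of 3.38 (q 0.139). With 29 lists, 1.45 would reach percentile 95 by chance, and with a gene-end window of 3 kb this list had 7 of 14 genes and percentile 92.5. None of its 6 gene-end peaks passed q under 0.05.

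Bile acid transport had 3 of 19 genes with a gene-end peak in the high list (percentile 44.9) and none with one in the low list (percentile 24.5). ABCB4, the phospholipid flippase of the bile canaliculus, had a fold of 4.70 (q 0.0106) at chromosome 9, 93171490 to 93171942, on 13 fragments. SLC51B, a basolateral bile acid exporter subunit, had 3.37 (q 0.168) and SLC10A2, the apical sodium-dependent uptake carrier, 2.24 (q 0.711). ABCB11, the bile salt export pump, had no gene-end peak. Within 10 kb of the gene, at chromosome 15, 75402296 to 75487092, the high list held a peak of fold 4.27 (q 0.031) that starts at 75489794, outside the gene, and an internal peak of fold 2.34, while the low list held an internal peak of fold 3.64 (q 1). SLC10A1, the main sinusoidal bile acid uptake carrier, had 2 low-list peaks within 10 kb, of fold 3.27 and 2.68 (q 1 for both), and no high-list peak. Of 22 bile acid signalling genes, 3 had a gene-end peak in the high list (percentile 30.0) and 2 in the low list (percentile 88.9). The former included NR1H3, which encodes LXR alpha, with a fold of 3.69 and NR1I2, which encodes PXR, with 2.63, and the latter were RXRB and PPARA. NR1H4, which encodes the bile acid receptor FXR, its target NR0B2 and CYP8B1 had no peak within 10 kb in either list. Of 12 detoxification genes, only UGT2B31 had a gene-end peak, of fold 2.61 in the high list (percentile 19.6).

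Lactate metabolism was compared because the mark derives from lactate. Of 32 glycolysis and lactate genes, 8 had a gene-end peak in the high list (percentile 80.3) and 3 in the low list (percentile 93.0). With the whole gene body counted, the numbers were 15 (percentile 76.7) and 8 (percentile 99.0). High-list examples were HIF1A, the hypoxia-inducible transcription factor, with a fold of 3.41, the lactate transporter SLC16A1 with 3.03 and the liver pyruvate kinase PKLR with 2.60. The low-list members were GPI, PFKL and ENO1. LDHA, which encodes a lactate dehydrogenase subunit, had 1 high-list peak, 4361 bp outside the gene, with a fold of 2.34 (q 0.548), and none in the low list. Of 21 genes in the list of lactylation writers and erasers, 4 had a gene-end peak in the high list (percentile 56.4). They were SIRT3 with a fold of 3.69, HDAC1 with 3.09, CREBBP with 2.60 and HDAC3. In the low list 1 had one, HAGH, which like GLO1 is a glyoxalase gene on that list rather than a writer or eraser. EP300, a candidate writer, had no peak within 10 kb in either list.

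Other liver programmes lay between percentiles 5 and 95 for gene-end peaks in the high list. Oxidative stress genes had 5 of 15 members with a peak (percentile 89.8), with folds of 3.69 for SOD2, 3.64 for GCLM and 3.12 for PRDX1. Lipid and cholesterol genes had 6 of 24 (percentile 79.6), led by DHCR7, the last enzyme of cholesterol synthesis, with 4.35 (q 0.031), FABP1 with 3.49 and SREBF1 with 3.12. When the whole gene body was counted in place of gene ends, 15 of the 24 had a high-list peak (percentile 97.6). Apoptosis and ER stress had 4 of 20 (percentile 57.2; CDKN1A 3.79, EIF2AK3 3.64, FAS 2.84), and inflammation 5 of 24 (percentile 58.1; MYD88 2.94, NFKBIA 2.94, NFKB1 2.68). Fibrosis had 3 of 17 (percentile 49.9; SMAD3 4.26 with q 0.0179, FN1 2.68, TGFBR2 2.37). Gluconeogenesis and urea cycle had 2 of 14 (percentile 35.1; ASL 3.09, GLS2 3.36), and cell cycle had 2 of 16 (percentile 27.3; CDK4 2.88, RB1 2.60). For gene-end peaks, no list reached percentile 95 in the low list, and a count of 0 there stood at percentile 11.9 or higher, which kept percentile 5 out of reach for most lists. For gene bodies in the low list, glycolysis and lactate genes and keratins (5 of 35, percentile 98.1) passed percentile 95.

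Cell type markers were counted in the same way. Of 20 hepatocyte markers, 1 had a gene-end peak in the high list (percentile 4.3), TTR with a fold of 2.21 (q 0.711), and none in the low list (percentile 23.6). With the whole gene body counted, 7 of the 20 had a high-list peak (percentile 50.8), and with unmatched random lists the gene-end count stood at percentile 5.78. ALB, the albumin gene, had no peak within 10 kb in either list. Kupffer and myeloid markers had 0 of 16 in the high list (percentile 1.64) and 1, AIF1, in the low list, and stellate and fibroblast markers had 0 of 11 (percentile 5.26). Cholangiocyte markers had 3 of 11 (percentile 75.8; SCTR 2.85 and CLDN4 2.63 among them). Endothelial markers had 2 of 12 (percentile 49.7; FLT1 4.27 with q 0.031, CDH5 3.69), lymphocyte markers 3 of 14 (percentile 61.3; CD3D and CD3G with 1 shared peak of 3.10, CD79B 2.94) and erythroid markers 1 of 8 (percentile 35.5; SLC4A1 4.12 with q 0.0399). Hepatocyte markers, Kupffer and myeloid markers, keratins and taste receptors were the 4 of 29 lists at or below percentile 5. The taste receptor list was set to hold vomeronasal receptors too, but none was measured. By chance 1.45 would lie there if every list could reach it, which stellate and fibroblast markers could not even with 0 members. At the length of the low list these 4 lists had 0 members, which stood at percentiles 6.76 to 20.3 and so could not reach percentile 5. With a window of 3 kb and with unmatched random lists 3 lists lay there, and with gene bodies 5 did. These 5 were stellate and fibroblast markers (percentile 1.03), complex I (1.13), Kupffer and myeloid markers (1.23), keratins (1.26) and taste receptors (1.31).

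**Figure D4:**
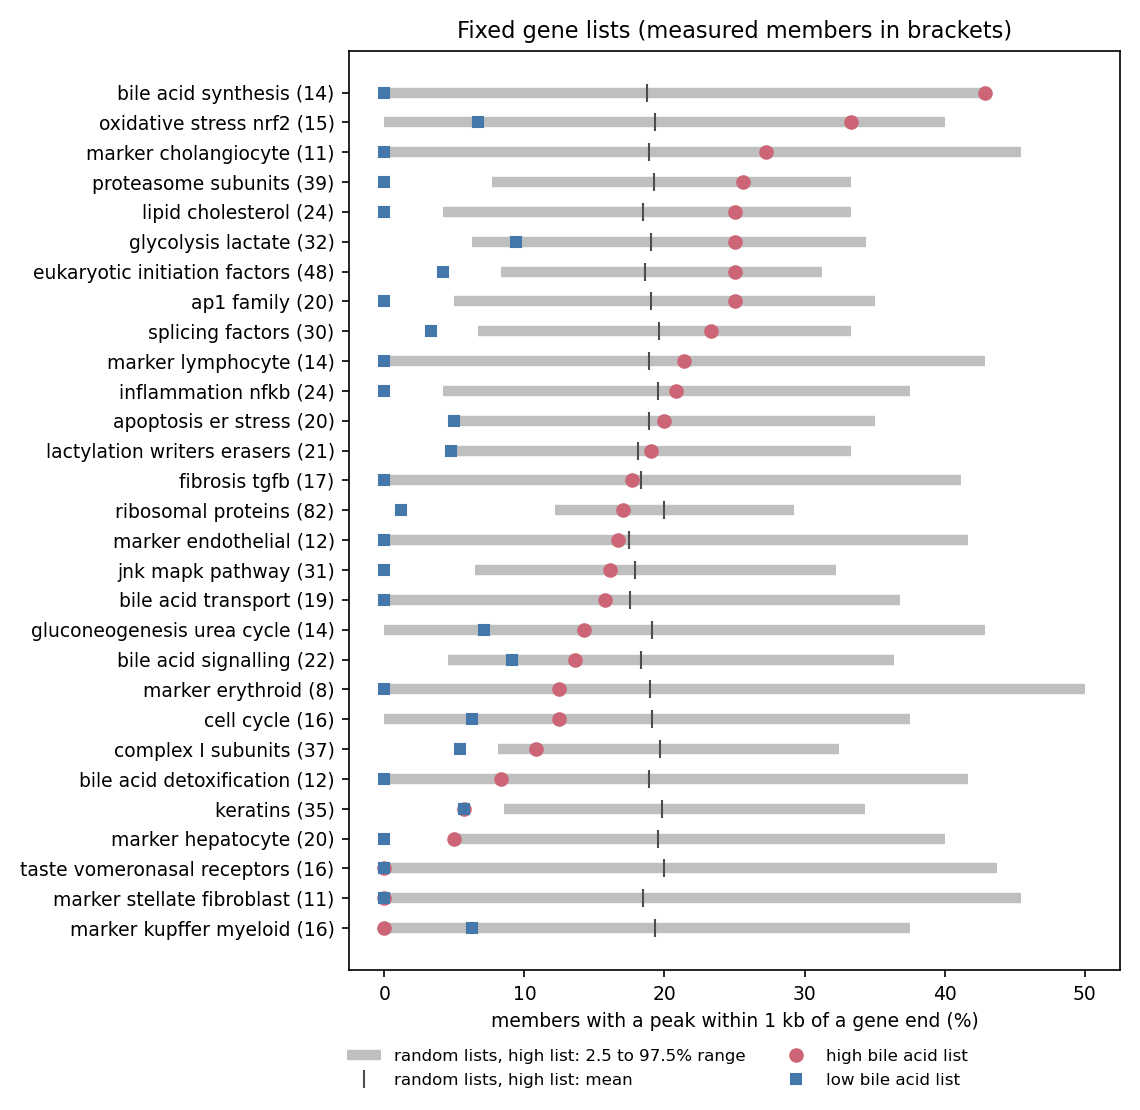
Share of the measured members of each gene list with a peak within 1 kb of a gene end, in percent (x axis), for the high (red circles) and low (blue squares) bile acid lists; grey bars span the central 95% of random lists for the high list and ticks mark their mean. Bile acid synthesis stands highest at 42.9% in the high list, while hepatocyte markers stand at 5.0%; counts over whole gene bodies are not drawn.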

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

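The alternatives below were planned before the data were examined, except the threshold of q under 0.05, the moves of 50 to 500 kb and the removal of peaks over high input, which were chosen after the data were seen. No paired analysis was possible because each group has 1 immunoprecipitated library and replicate numbers were given in accession order. At q of 1e-05 or smaller, the low list kept 5 peaks and the high list 10; overlaps were 100% and 50% of them, gene ends held 0% in both, 0 genes fell in both, high only or low only, 0 lists passed percentile 95 or 5, and JUN had 0 high-list peaks. At a fold of 4 or more, 79 and 891 peaks were left, 1.27% and 0.112% overlapped, 20.3% and 16.8% lay at gene ends, and 0, 162 and 15 genes were in both, high only and low only. At q under 0.05, 13 and 608 peaks were left, 46.2% and 0.987% overlapped, 0% and 20.1% lay at gene ends, and 0, 133 and 0 genes were in these classes; 2 lists reached percentile 95 on 1 gene each, endothelial and erythroid markers, and 0 lay at percentile 5. These falls in number come with the shorter lists. The overlaps at q of 1e-05 were 5 of 5 low-list and 5 of 10 high-list peaks. At q under 0.05 they were 6 of 13 and 6 of 608, including the same 5. Of the peaks left at q of 1e-05, all 10 in the high list lay over an expected pileup above 5 times the genome-wide average background. In the low list 4 of the 5 did. The overlaps at these thresholds therefore rest largely on places of high input. With the high list at the length of the low list, 0.837% of the low list overlapped, 13.9% of the high list lay at gene ends, 40 and 805 genes were in both and high only, and 0 lists lay at or below percentile 5, which the 4 lists that lay there before could not reach with a count of 0. A reciprocal overlap of 50% left 1.94% and 0.392% shared, 4.62 times chance over 100 placements, and 30 genes in both; peaks within 1 kb raised the shares to 8.16% and 1.73%. Moves of 50 to 500 kb put the overlap at 2.88 times chance. A window of 3 kb gave 21.0% and 22.5% at gene ends, 437 and 4662 genes in both and high only, and 0 lists at percentile 95, and one of 500 bp gave 5.68% and 6.25% and 74 genes in both. Within 100 kb, JUN had 3 high-list peaks. Where no count of peaks explains a change, the cause was not tested. The overlap was above random placement in the settings where it was computed, which were reciprocal overlap, equal length and moves of 50 to 500 kb; it was not computed in the others, and at q of 1e-05 few peaks were left. Restricting to assembled chromosomes and merging peaks changed neither list, and leaving out peaks over high input left the overlaps at 3.49% and 0.704%. Of 174 counts of members per list under alternatives, 108 differed from the main count by over 1.5 times. The bile acid synthesis list stayed above percentile 95 with the equal-length list (99.7) and unmatched random lists (98.1) but not with gene bodies (94.7), where lipid and cholesterol genes passed it (97.6), or 3 kb (92.5). Shuffling outside assembly gaps, matching on GC content, and the motif and repeat shares with their alternatives were not run. Depth limits single peaks, since the caller accepted 7 fragments in the low library and 6 in the high library over the genome-wide average background, the lowest it uses.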

Other observations

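The tests of explanations in this part were chosen after the results were seen, while the counts of gene families and the high list at equal length were planned. Proteasome subunits had a gene-end peak in the high list for 10 of 39 members (percentile 84.1), with folds of 3.38 for PSMD4, 3.20 for PSMB11 and 3.17 for PSMB5. Eukaryotic initiation factor symbols had 12 of 48 (percentile 87.0), led by EIF2AK3, a kinase of eIF2, with 3.64, EIF2B2 with 3.49 and EIF4G1 with 3.46. Splicing factors had 7 of 30 (percentile 70.3; SRSF3 3.58, SNRPA1 3.36, SRSF6 3.28) and ribosomal proteins 14 of 82 (percentile 25.9; RPS7 4.36 with q 0.031, RPL19 3.69, RPS9 3.69). Subunits of respiratory complex I had 4 of 37 (percentile 8.59, and 1.13 with gene bodies; NDUFB7 3.23 and NDUFA13 2.80 among them). Keratins had 2 of 35 (percentile 1.38, with KRT77 and KRT79 both at 2.60), and taste receptors 0 of 16 (percentile 1.57). In the low list these families had 0, 2, 1, 1, 2, 2 and 0 members with a peak, in the same order.

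The high list held 4.93 times as many peaks as the low list. Fewer immunoprecipitated fragments in the low library are argued against as the cause, because that library held 1.097 times the fragments per kb of the high library. That ratio takes the genome size set in the caller to be the same for both lists. The caller's scaling of the low library to its smaller input is a candidate explanation for part of the gap. In 5 simulated unenriched libraries for each of 4 settings, the high settings gave 2.66 to 4.09 times as many peaks as the low settings, and 1.23 to 1.31 times without the factor of 0.881. These libraries gave 0.6 to 2.86 peaks per Mb with the low settings and 2.45 to 7.6 with the high settings. Observed densities were 2.36 and 11.6. The low list exceeded simulated background in 3 of the 4 settings and the high list in 4. The unevenness of coverage in these settings was not fitted to the data, and simulated density rose with it. The comparison therefore does not show that either list stands above background. More H4K12la in the high bile acid liver stays open and cannot be told apart from a difference between these 2 libraries: the 13.9% of summits at gene ends in the high list at equal length decides nothing, since that share rises with rank by p in both lists.

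Chromosome X held 53 peaks of the high list and 4 of the low list, where the autosomal density would give 1569 and 319; Y held 8 and 1. Few genes on X are argued against as the cause, because the 6 autosomes with fewer genes per Mb than X had at least 8.76 high-list peaks per Mb, against 0.421 on X. X at a lower copy number outside its tip, as in male tissue, is a candidate explanation despite the female label: 24 of the 53 high-list peaks (45.3%; 31.6 to 59.6%) lay in the first 10 Mb, the part that holds the pseudoautosomal region and makes up 7.94% of the length, and in the low list 1 of 4 did. These first 10 Mb were themselves sparse, at 2.4 high-list peaks per Mb against 12.5 on autosomes, whose sparsest 10 Mb bin had 2.9. The low list had 0.1 there against 2.53. The last of the 24 summits lay at 6429931, and the next high-list summit on X at 18117201. The 10 Mb may thus reach beyond the pseudoautosomal region, whose end was not determined here. Their low density therefore does not decide whether a lower copy number outside the tip accounts for it. Less H4K12la on X over normal input cannot be told apart from a lower copy number. Of high-list X peaks beyond 10 Mb, 72.4% had the caller's genome-wide average as their expected pileup, so no higher local input, against 20.6% on autosomes. A weaker immunoprecipitation alone would also favour such places. How well reads map to X was not tested, as no genome sequence was used here.

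The strongest peaks by p lay where the input was also high. Of the 10 strongest high-list peaks, 10 had an expected pileup over 5 times the genome-wide average, as did 4 of the 10 strongest low-list peaks, against 0.117% and 0.139% of all peaks. The strongest in both lists sits near the end of chromosome Y, at 43257579 to 43258017 in the high list, with 2382 fragments over 1225 expected and a fold of 1.94. Ranking by p favours such places whatever the cause, and of the 10 peaks of highest fold 0 were of this kind in either list, so whether sequence present in more copies than the assembly shows gives these peaks was left open, and no biological explanation was tested.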
